A study of Mus musculus with 12 samples.

How the data were processed

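The samples were whole testes of mice on a C57BL/6, 129S5, SvEvBrd hybrid background at postnatal day 7. Per the labels' protocols, tissue was kept in RNAlater, RNA was purified on RNeasy columns with DNase on the column, and 3 testes, each from another animal, were pooled for each array. Labelled RNA was made with an oligo(dT) primer carrying a T7 promoter, so signals come mostly from the 3' part of transcripts. There were 12 arrays in 3 groups of 4: wild type, Sohlh1 knockout and Sohlh2 knockout. Groups and replicate numbers were taken from the sample titles.

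The values in the deposited table are signal intensities on a linear scale, made with MAS5 and GCOS per the submitters' processing notes. Versions and settings of those tools are not given in the sources used here. The table itself shows that each array has the same trimmed mean (2% removed at each end), while array medians and upper quartiles differ. It holds no detection calls. Array medians were 76.6 to 90.8, and 26469 to 28348 of 45101 probe sets per array lay above the filter value below. The number of arrays limits the precision.

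Intensity was turned to log2(value + 14.2), where 14.2 is the 20th percentile of all non-control values, and no further normalization was applied. All log2 fold changes are on that scale, where the offset draws those of dim genes towards 0. The 64 control probe sets were left out. A probe set was tested if it lay above 48.6, the 40th percentile, on at least 4 of the 12 arrays, which 28694 did. Gene symbols came from the platform's annotation: of the other 45037 probe sets 34945 had exactly 1 symbol, 932 had several and 9160 had none and are unnamed here. Symbols were compared by Entrez identifier with the RefSeq gene table of assembly GRCm38.p6, which matched 34741 of them and changed 0 symbols. Each of 13702 genes was represented by its probe set with the highest mean. Coordinates are not printed, since no genome build is named for the array.

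Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), two-sided, in 1 fit of all 12 arrays with genotype as the only term. P-values were adjusted by Benjamini and Hochberg over all genes tested, and changed, rose and fell mean an adjusted p under 0.05. The contrasts were each knockout against wild type, and Sohlh2 knockout against Sohlh1 knockout. P-values measure the spread between pools of 3 testes. Figures were drawn with matplotlib 3.10.9.

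Before the data were examined, the rule for named genes and 20 gene lists were fixed, the lists for stages of germ cells, other cells of the testis, and pathways. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and does not compare the list with other genes. Lists could share genes, so their results are not independent. Crabp1 and Stra8 were on the lists of differentiating spermatogonia and of the retinoic acid pathway. Etv5, Bcl6b, Lhx1, Id4, T and Pou3f1 were on those of undifferentiated spermatogonia and of GDNF-regulated genes. A list of mast cell genes was added later. The rule for named genes took Sohlh1 and Sohlh2, the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap, and up to 4 members of each list with the smallest p, with 5 and 5 for the comparison between knockouts. Genes with only a clone-like identifier counted in the ranking and could be left unnamed. List members named beyond those 4, and Magea5, Mageb3, Cap1, Zfp386 and the mast cell genes, were chosen after their values were seen.

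The steps were tested on simulated data with the means and spread of these arrays. Among 13702 genes 200 were changed in the simulated Sohlh1 comparison, in equal parts at 1.5-fold, 2-fold, 3-fold and 4-fold. The fit recovered 64% of the part at 1.5-fold, 78% at 2-fold, 94% at 3-fold and 98% at 4-fold, with 7 unchanged genes called. Values were drawn from normal distributions, without links between genes and without arrays that stood apart. Overlap of the knockout comparisons, which share the wild-type arrays, was set beside 100 simulated draws and beside fits with the wild-type arrays split 2 and 2.

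Alternatives tried were other log offsets, quantile normalization, median centring, other filters, other choices of probe set, eBayes without trend, array weights, fits of only 2 groups, the replicate number as a block, stricter thresholds, and leaving out each array in turn. Added after seeing the data were fits without the 2 arrays whose targeted genes went against the labels, without the 2 arrays of high 3' to 5' control ratio, without all 3 of these arrays, and with that ratio as a covariate. Samples were never moved between groups on the basis of their values. Detection calls and scanner files were not used here.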

Results

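RNA from whole testes of mice at postnatal day 7 was hybridised to 12 Affymetrix whole-genome mouse arrays, which carry sets of short oligonucleotide probes. There were 3 groups of 4 arrays: wild type, homozygous Sohlh1 knockout and homozygous Sohlh2 knockout. Sohlh1 and Sohlh2 encode basic helix-loop-helix transcription factors made in germ cells. Each array held RNA pooled from 3 testes, 1 per animal, so a group stood for 12 animals and the spread between arrays was a spread between pools. The values were MAS5 signals, scaled to the same trimmed mean on every array, with medians between 76.6 and 90.8. The number of arrays limits the precision of each value. The comparisons asked which transcripts differ when either factor is missing, and whether the losses of the 2 factors differ from each other.

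The targeted genes were read first, since they check the labels. Each had 1 probe set, and the labels do not say whether that probe set lies inside the deleted part of the gene, so a low signal is a check only if it does. Sohlh1 had a mean signal of 1174 ± 50.9 (SD, n = 4) in wild type and lay between 50.2 and 104 on the arrays labelled Sohlh1 knockout 2, 3 and 4. The array labelled Sohlh1 knockout 5 gave 595 for Sohlh1, and the array labelled Sohlh2 knockout 1 gave 126. Sohlh2 had a mean of 1050 ± 134 (SD, n = 4) in wild type. It read 157, 93.6 and 73.2 on the arrays labelled Sohlh2 knockout 3-1, 4 and 5, but 1847 on the array labelled Sohlh2 knockout 1. On the array labelled Sohlh1 knockout 5 Sohlh2 read 94.4, against 1556 to 1783 on the other 3 arrays of that label. The targeted genes thus went against the labels on 2 arrays, those labelled Sohlh1 knockout 5 and Sohlh2 knockout 1. Every group below is the group as labelled.

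With the arrays as labelled, Sohlh1 had a log2 fold change of -3.12 (SE 0.54, limma adjusted p = 0.00298) in the Sohlh1 knockout. Sohlh2 had a log2 fold change of -2.18 (SE 0.86, adjusted p = 0.195) in the Sohlh2 knockout and did not pass the threshold; without the array labelled Sohlh2 knockout 1 it passed at -3.17 (adjusted p = 0.0141). Among all tested probe sets the adjusted p-values were 0.0118 and 0.309. Leaving out the 2 arrays whose targeted genes went against the labels, a choice made after seeing the data, left means over 3 arrays per knockout. Those arrays were picked by their Sohlh1 and Sohlh2 values. Fold changes and p-values of these genes without either array are therefore no test of them. Sohlh1 then stood at 6.11% of wild type in the Sohlh1 knockout and at 43.2% in the Sohlh2 knockout, and Sohlh2 stood at 10.3% of wild type in the Sohlh2 knockout. In the Sohlh1 knockout Sohlh2 was at 157% of wild type, and its log2 fold change turned from -0.33 (adjusted p = 0.879) to 0.65 (adjusted p = 0.0481). Without the array labelled Sohlh1 knockout 2 as well, which had a high 3' to 5' control ratio, that value was 0.69 and did not pass (adjusted p = 0.0854).

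**Figure D1:**
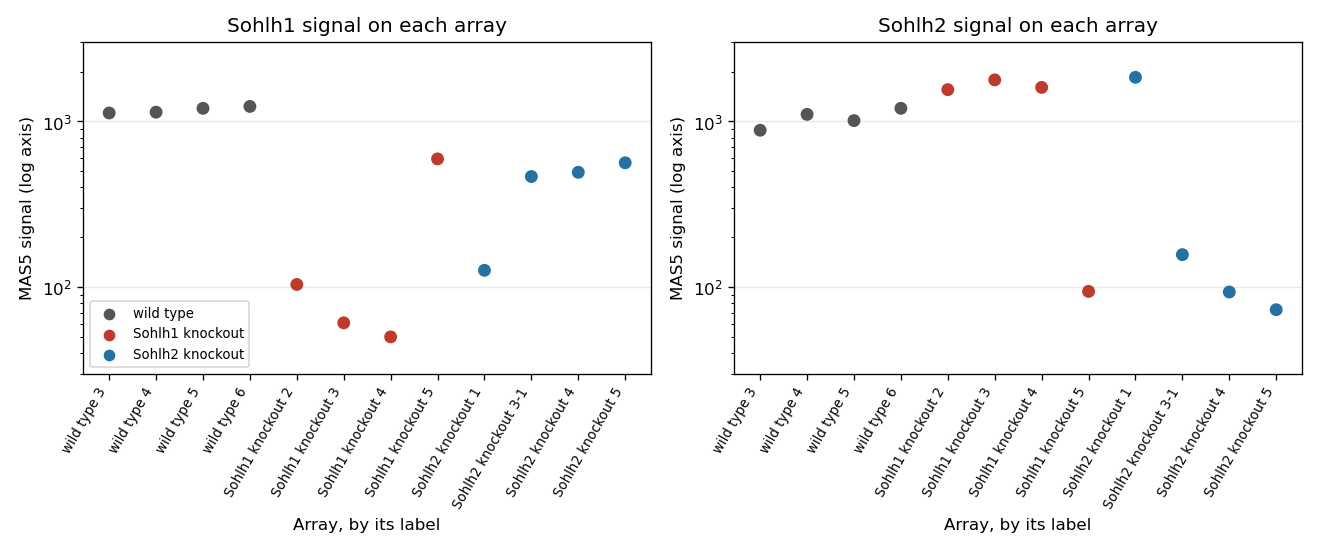
MAS5 signal of Sohlh1 (left) and Sohlh2 (right) on each of the 12 arrays, named by its label, on a log axis; each point is 1 array and colour gives the labelled group. On the array labelled Sohlh1 knockout 5 Sohlh2 was at 94.4 and Sohlh1 at 595, and on the array labelled Sohlh2 knockout 1 Sohlh2 was at 1847 and Sohlh1 at 126.

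In the Sohlh1 knockout, genes of differentiating spermatogonia were lower than in wild type. Crabp1, which binds retinoic acid, fell from 3011 ± 363 to 537 ± 108 (SD, n = 4 each; log2 fold change -2.47, SE 0.13, adjusted p = 3.29e-08). Kit, the receptor carried by differentiating spermatogonia, fell from 1739 ± 176 to 453 ± 91.2 (log2 fold change -1.92, SE 0.15, adjusted p = 1.27e-06). The transcription factor Dmrtb1 fell from 701 ± 42.0 to 113 ± 23.7, and Lhx8, a transcription factor of oocytes, from 260 ± 29.1 to 22.5 ± 10.1. On the other side, Dppa4 rose from 414 ± 50.6 to 1058 ± 44.6 (log2 fold change 1.33, SE 0.10, adjusted p = 7.45e-07).

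The 10 largest falls were those of Sohlh1 itself, Lhx8, Dlx1, Dmrtb1, Crabp1, Tbx1, Foxn4, Esx1, Slc27a2 and Lmo1, from -3.12 to -2.00 on the log2 scale. Slc27a2 encodes an acyl-CoA synthetase of fatty acid uptake. The order of these falls holds at the log offset used, since Lhx8, Dlx1 and Foxn4 had knockout means (22.5, 6.23 and 22.5) below the filter value of 48.6, and without an offset Dlx1 had -4.85. The 10 largest rises were those of Hdgfl1, Aox4, Npy, Rrad, Cldn34b2, Arhgap9, Magea6, Dppa4, Selp and Sox30, from 1.82 down to 1.25, an order that likewise holds at this offset, since the wild-type means of all but Rrad, Magea6, Dppa4 and Sox30 lay below 48.6. Rrad, a small GTPase, rose from 111 ± 23.4 to 331 ± 20.2, and Magea6, of the MAGE family, from 136 ± 29.0 to 384 ± 9.71. Npy lost the threshold without wild type 3, 4 or 5 or without the array labelled Sohlh1 knockout 2, 3 or 5, with adjusted p up to 0.106. Cldn34b2 lost it without the array labelled Sohlh1 knockout 3 (adjusted p = 0.0519). Arhgap9 lost it with the mean of all probe sets of a gene (0.92, adjusted p = 0.109), and Arhgap9, Npy, Cldn34b2, Selp and Sox30 lost it without the 3 arrays that had targeted genes against the labels or a high 3' to 5' control ratio (adjusted p from 0.0846 to 0.172).

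Of the 15 measured genes on the list of differentiating spermatogonia 8 fell and none rose, with a median log2 fold change of -0.58 (camera adjusted p = 2.08e-16; adjusted p = 0.00577 with an estimated correlation). Crabp1, Kit, Dmrtb1 and the X-linked homeobox gene Esx1 had the smallest p-values among them, and Stra8 had -0.46 without passing (adjusted p = 0.0590). Adjusted over the list alone, 10 fell. Of 24 cell cycle genes 9 fell and none rose, among them the mitotic kinases Aurkb (-0.72) and Plk1 (-0.68), cyclin A2 (Ccna2, -0.68) and the ribonucleotide reductase subunit Rrm2 (-0.68). That list had a median of -0.30 (camera adjusted p = 1.38e-11; adjusted p = 0.0327 with an estimated correlation), and 12 of its genes fell when adjusted over the list alone. Of 10 oocyte genes 4 fell, which were Lhx8, Figla, Nobox and Dppa3 (list median -0.62, camera adjusted p = 2.76e-05; adjusted p = 0.00962 with an estimated correlation), also 4 adjusted over the list alone. The oocyte list held 19 genes, of which 2 had no named probe set and 7 were too dim to be tested. The result thus covers only the 10 tested. The oocyte median was -0.40 without the 3 arrays of doubted label or high 3' to 5' ratio, -0.97 without a log offset and -0.27 with an offset at the median. Nobox lost the threshold without wild type 4, 5 or 6 or the array labelled Sohlh1 knockout 2 or 4 (adjusted p up to 0.0926), and Dppa3 without wild type 6 (adjusted p = 0.0615).

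The lists of cholesterol synthesis and the retinoic acid pathway passed camera downward, and neither passed with an estimated correlation. Mvd and Lss fell among 17 cholesterol genes (median -0.18, camera adjusted p = 0.0139; adjusted p = 0.131 with an estimated correlation; 5 fell adjusted over the list alone). Lss lost the threshold without wild type 5 or 6 or the array labelled Sohlh1 knockout 3 or 4 (adjusted p up to 0.0800), and with probe sets that can match several transcripts left out another probe set stood for it at 0.18. Crabp1 and Rbp4, a retinol carrier, fell among 14 retinoic acid genes (median -0.13, camera adjusted p = 0.0234; adjusted p = 0.131 with an estimated correlation; 3 fell adjusted over the list alone). Crabp1 and Stra8 were also on the list of differentiating spermatogonia, so the results of these lists are not separate. The retinoic acid call ended without the array labelled Sohlh1 knockout 5 (median -0.046, adjusted p = 0.0635). The median of the retinoic acid list was -0.0014 without the array labelled Sohlh1 knockout 2, which had a high 3' to 5' ratio. It was -0.081 or -0.079 without wild type 4 or 5 and -0.23 without the array labelled Sohlh1 knockout 4. Without the 3 arrays of doubted label or high ratio it was 0.0033 (camera adjusted p = 0.210).

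Genes of undifferentiated spermatogonia moved both ways. Of 24 measured, 6 rose and 3 fell (8 and 5 adjusted over the list alone), and the list did not pass (median 0.23, camera adjusted p = 0.254). Gfra1, a receptor of the growth factor GDNF, rose by 0.97 and Id4 by 0.82 on the log2 scale. Sox3 fell by 1.11, Neurog3 by 1.19 and Pou3f1 by 0.85. With the mean of all probe sets of a gene Gfra1 had 0.54 (adjusted p = 0.420). Without the array labelled Sohlh1 knockout 2 the list passed (adjusted p = 0.0456), and Pou3f1 lost the threshold without wild type 4 or the array labelled Sohlh1 knockout 4 (adjusted p up to 0.0571).

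Lists of other cells and processes did not pass in the Sohlh1 knockout. Of 18 genes of germ cells at any stage 2 rose, Dppa4 and Stk31 (0.50), and 3 fell, among them Tex11 (-1.04); the median was -0.20 (camera adjusted p = 0.0802; 3 rose and 4 fell adjusted over the list alone). That list passed without wild type 3 or without the array labelled Sohlh1 knockout 5 (adjusted p down to 0.0278). The lists of Sertoli cells (median 0.15, camera adjusted p = 0.0743), Leydig cells (0.09), peritubular muscle (-0.10), endothelium (-0.03), leukocytes (-0.06), erythroid cells (0.01) and adipose tissue (0.20) held 1 changed gene, Dmrt1 at -0.28, which lost the threshold in 11 of 12 fits that left out 1 array (adjusted p up to 0.139). Some of these medians changed sign with 1 array left out. They ran from -0.16 to 0.49 for adipose tissue, -0.16 to 0.10 for leukocytes, -0.10 to 0.17 for erythroid cells and -0.05 to 0.10 for endothelium. The Sertoli list passed under 7 of 31 alternatives. These were leaving out wild type 3 (camera adjusted p = 0.0463), fry (adjusted p = 0.00664), the fit of only the 2 groups compared, the 3' to 5' ratio as a covariate, both replicate blocks, and leaving out probe sets that can match several transcripts. Of 22 meiosis genes 2 rose, Mnd1 (1.10) and Hormad1 (0.74), and 4 fell, among them Syce1 at -0.51 (median 0.10, camera adjusted p = 0.822). Of 15 piRNA pathway genes 4 rose, among them Gtsf1 (0.83), and 1 fell, Pld6 at -0.62 (median -0.15, camera adjusted p = 0.933). That median ran from -0.17 to 0.014 with 1 array left out.

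The remaining lists did not pass either in the Sohlh1 knockout. GDNF-regulated genes had a median of 0.17 (camera adjusted p = 0.190), apoptosis genes 0.00 (adjusted p = 0.822), immediate early genes 0.07 (adjusted p = 0.740) and ribosomal proteins 0.13 (adjusted p = 0.0743). Id4 rose and Pou3f1 fell on the first of these, and Bid fell by 0.56 among 13 apoptosis genes. Bid lost the threshold without wild type 5 or 6 or the array labelled Sohlh1 knockout 2 or 5 (adjusted p up to 0.0782), and the ribosomal list passed without wild type 5 or 6 or the array labelled Sohlh1 knockout 5 (adjusted p down to 0.00562). Median, mean and test differed in sign for the piRNA (mean 0.03, test down), meiosis (0.03, down), apoptosis (0.01, down), endothelium (0.06, up) and erythroid (-0.07, down) lists.

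In all, 609 of 13702 genes changed between the Sohlh1 knockout and wild type, 241 higher and 368 lower, with 33 at least 2-fold higher and 68 at least 2-fold lower. Over all tested genes, 1853 (13.5%) had the 4 arrays of one group apart from the 4 of the other, an arrangement that chance gives for 2.86%. With median centring of the arrays the changed genes were 236 higher and 260 lower. The count was 368, 335 or 322 without wild type 4, 5 or 6, 370 without the array labelled Sohlh1 knockout 4 and 970 without the array labelled Sohlh2 knockout 1. It was 776 without both arrays whose targeted genes went against the labels.

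**Figure D2:**
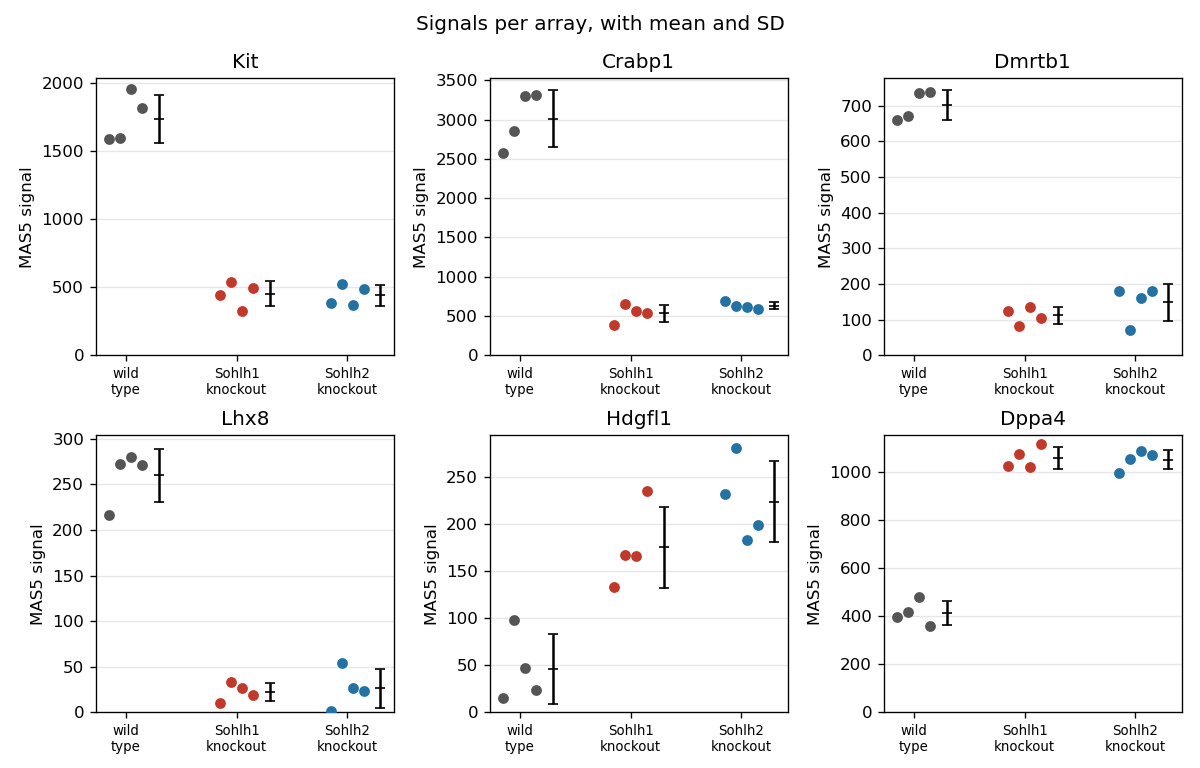
MAS5 signal of 6 genes on each array, grouped by label; points are arrays (4 per group) and the black mark and bar beside them are the mean and SD. Kit, Crabp1, Dmrtb1 and Lhx8 were lower on all 8 knockout arrays than on all 4 wild-type arrays, and Hdgfl1 and Dppa4 were higher.

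In the Sohlh2 knockout, Crabp1 fell from 3011 ± 363 to 633 ± 44.8 (SD, n = 4 each; log2 fold change -2.22, SE 0.13, adjusted p = 1.59e-07), and Kit from 1739 ± 176 to 442 ± 76.6 (log2 fold change -1.95, SE 0.15, adjusted p = 1.10e-06). Lhx8 fell from 260 ± 29.1 to 26.5 ± 21.4, and Dmrtb1 from 701 ± 42.0 to 149 ± 52.5. Hdgfl1 rose from 46.0 ± 37.0 to 224 ± 43.2 (log2 fold change 2.16, SE 0.32, adjusted p = 0.00100), and Dppa4 from 414 ± 50.6 to 1051 ± 38.7.

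The 10 largest falls were those of Lhx8, Dlx1, Crabp1, Dmrtb1, Runx3, Tbx1, Esx1, Ovol1, Kit and Slc27a2, from -2.93 to -1.92 on the log2 scale. The knockout means of Lhx8, Dlx1, Runx3 and Ovol1 lay below the filter value of 48.6. The 10 largest rises were those of Hdgfl1, Dppa2, Rrad, Tbx4, Aox4, Mmp9, Hoxb6, Treml1, Kcnip2 and Mypn, from 2.16 down to 1.57. The wild-type means of all but Rrad and Mmp9 lay below 48.6, so the order in both directions holds at the log offset used: without one, Hoxb6 had 2.98 and Tbx4 2.96, above Hdgfl1 at 2.62. Rrad rose from 111 ± 23.4 to 383 ± 56.1, and Mmp9, a secreted matrix protease, from 56.9 ± 29.8 to 195 ± 67.7. Dppa2, Tbx4, Hoxb6 and Treml1 each lost the threshold in 5 to 8 of the 12 fits that left out 1 array, with adjusted p up to 0.118 (Treml1 without wild type 6). Kcnip2 lost it without the array labelled Sohlh2 knockout 4 (adjusted p = 0.0516). Dlx1 and Ovol1 lost it without a log offset (adjusted p = 0.0852 and 0.0758), and Runx3 with the mean of all probe sets of a gene (-0.84, adjusted p = 0.296).

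Of the 15 genes of differentiating spermatogonia 7 fell and none rose, with a median of -0.43 (camera adjusted p = 2.18e-11; adjusted p = 0.0210 with an estimated correlation). Without the array labelled Sohlh2 knockout 1, which had targeted genes against its label and the highest 3' to 5' ratio, the median was -0.73. Without all 3 doubted arrays the median was also -0.73 (camera adjusted p = 2.89e-12 at the preset correlation). The call ended there with an estimated correlation (adjusted p = 0.0594). The arrays labelled Sohlh1 knockout enter this comparison through the spread alone. Crabp1, Kit, Dmrtb1 and Esx1 were among them, and 9 fell adjusted over the list alone. Of 10 oocyte genes Lhx8, Figla and Dppa3 fell (median -0.45, camera adjusted p = 0.00211; adjusted p = 0.0448 with an estimated correlation, and 0.0989 without the 3 doubted arrays; 3 adjusted over the list alone). Again only these 10 of the 19 listed genes were tested. The oocyte median was -0.25 without the array labelled Sohlh2 knockout 4 and with an offset at the median, and -0.22 without a filter. Figla and Dppa3 each lost the threshold in 6 of 12 fits that left out 1 array, with adjusted p up to 0.123 and 0.112. Of 24 cell cycle genes 6 fell and none rose (8 adjusted over the list alone), among them Aurkb (-0.70), Plk1 (-0.68) and Rrm2 (-0.55). That list had a median of -0.14 and camera adjusted p = 1.41e-06, which became adjusted p = 0.113 with an estimated correlation; the median was -0.22 without the array labelled Sohlh2 knockout 1.

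Genes of undifferentiated spermatogonia had a median of 0.31 in the Sohlh2 knockout (camera adjusted p = 0.0144). The list did not pass with an estimated correlation (adjusted p = 0.434) or with fry (adjusted p = 0.0598). Its median was 0.20 without the array labelled Sohlh2 knockout 1 and 0.12, no longer passing, with the mean of all probe sets of a gene (adjusted p = 0.0564). Of 24, 5 rose and 3 fell, or 11 and 3 adjusted over the list alone. Gfra1 rose by 1.01, Id4 by 0.81 and the pluripotency factor Pou5f1 by 1.35 on the log2 scale. With the mean of all probe sets of a gene Gfra1 had 0.62 (adjusted p = 0.365). Sox3 fell by 1.00, Neurog3 by 0.98 and Pou3f1 by 0.84, the last losing the threshold without wild type 4 (adjusted p = 0.0729). The retinoic acid list was lower with Crabp1 and Rbp4 fallen (median -0.22, camera adjusted p = 0.00427, adjusted p = 0.10 with an estimated correlation, 3 fallen adjusted over the list alone). Its median was -0.14 without wild type 4 and -0.089 without the array labelled Sohlh2 knockout 3-1. The cholesterol list was lower with Mvd fallen (median -0.08, camera adjusted p = 0.0144; adjusted p = 0.201 with an estimated correlation; 4 fell adjusted over the list alone), and ended as a call without wild type 3 (adjusted p = 0.0814) and with array weights (adjusted p = 0.0750); its median was -0.043 without wild type 5 and -0.12 without the array labelled Sohlh2 knockout 1 or 5. Ribosomal proteins were higher with Rps6 risen among 16 (median 0.13, camera adjusted p = 0.0135; adjusted p = 0.852 with an estimated correlation). That call ended without wild type 3 or the array labelled Sohlh2 knockout 1 or 3-1 (medians 0.067, 0.078 and 0.073, adjusted p up to 0.294), with quantile normalization (0.039, adjusted p = 0.533) and with array weights (adjusted p = 0.0877), the median was 0.20 without the array labelled Sohlh2 knockout 5, and Rps6 lost the threshold in 9 of 12 such fits.

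The other lists did not pass in the Sohlh2 knockout. Of 18 genes of germ cells at any stage Dppa4 and Stk31 rose and Tex11 fell (median -0.04, camera adjusted p = 0.646; 3 rose and 1 fell adjusted over the list alone). Medians were 0.07 for Sertoli cells, -0.01 for Leydig cells, -0.01 for peritubular muscle, 0.03 for endothelium, 0.08 for leukocytes, -0.21 for erythroid cells and 0.08 for adipose tissue. With 1 array left out they ran from -0.13 to 0.21 for adipose tissue, -0.01 to 0.09 for endothelium and -0.05 to 0.13 for leukocytes. Those of Leydig cells and peritubular muscle also changed sign in such fits. Among these lists Dmrt1 (-0.32, Sertoli) and Actg2 (-0.46, peritubular muscle) fell. Dmrt1 lost the threshold without wild type 4 or 5 or the array labelled Sohlh2 knockout 3-1 or 5 (adjusted p up to 0.0805), Actg2 in 9 of 12 fits that left out 1 array (adjusted p up to 0.152), and both with median centring (adjusted p = 0.0862 and 0.0585). Of 22 meiosis genes 4 rose, among them Mnd1 (1.09) and Hormad1 (0.77), and 1 fell (median 0.14, camera adjusted p = 0.403), and the list passed without the array labelled Sohlh2 knockout 3-1 (adjusted p = 0.0469). Of 15 piRNA pathway genes 3 rose, among them Gtsf1 (0.99), and Pld6 fell by 0.79 (median 0.17, camera adjusted p = 0.703). GDNF-regulated genes had a median of 0.15 (camera adjusted p = 0.0969), with Id4 risen and Pou3f1 fallen, and passed without the array labelled Sohlh2 knockout 1 (adjusted p = 0.0313). Of 13 apoptosis genes Pmaip1 rose by 1.12, a call that ended in 5 of 12 fits that left out 1 array (adjusted p up to 0.0845), and Bid fell by 0.60, which ended without wild type 6 (adjusted p = 0.0601). Apoptosis genes had a median of -0.05 (adjusted p = 0.817; mean 0.04) and immediate early genes -0.04 (adjusted p = 0.703), and the adipose list had a mean of -0.08 with a test pointing down.

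In all, 514 genes changed between the Sohlh2 knockout and wild type, 219 higher and 295 lower, with 50 at least 2-fold higher and 52 at least 2-fold lower. Over all tested genes the groups lay apart in 1517 (11.1%), against 2.86% by chance. With median centring the changed genes were 192 higher and 199 lower. The count was 264, 287 or 286 without wild type 4, 5 or 6 and 274 without the array labelled Sohlh2 knockout 4. It was 485 without both arrays whose targeted genes went against the labels. The array labelled Sohlh2 knockout 1 also had the highest mean log2 ratio of 3' to 5' control probe sets, 2.71, followed by 1.26 on the array labelled Sohlh1 knockout 2 and 0.37 to 0.88 on the other 10. With that ratio in the model the differentiating list had medians of -0.72 in the Sohlh1 and -0.63 in the Sohlh2 knockout.

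**Figure D3:**
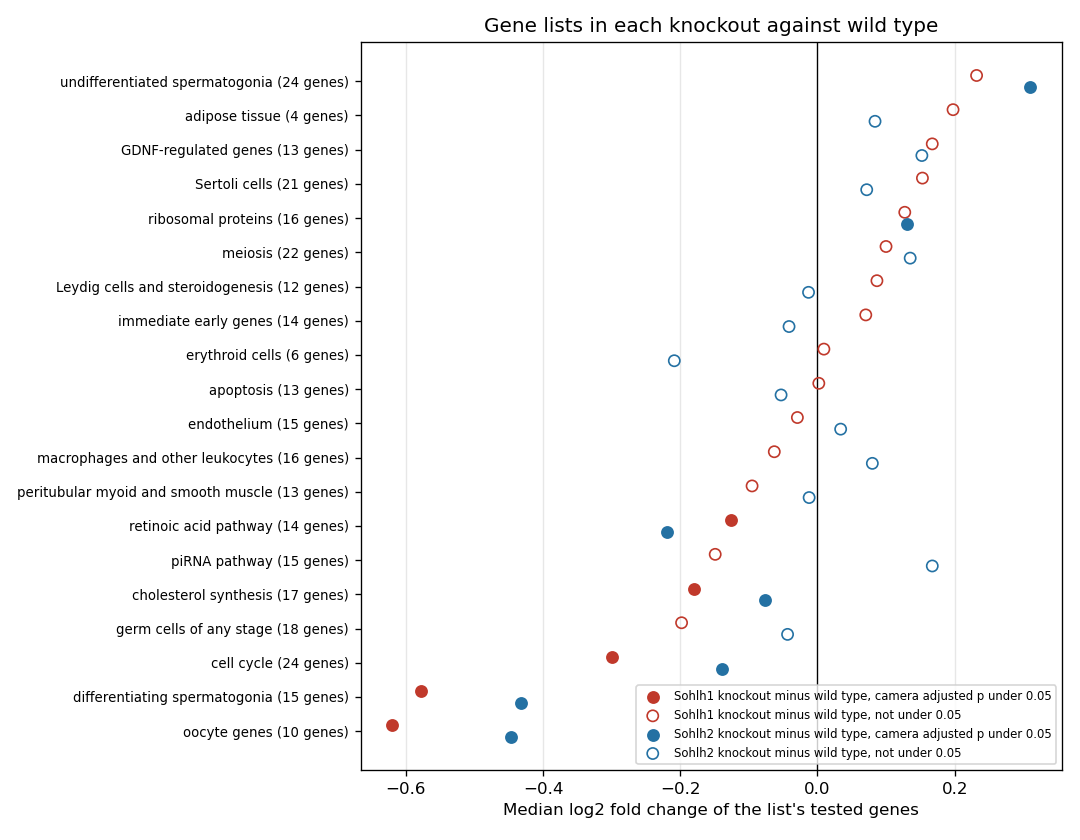
Median log2 fold change of the tested genes of each of 20 gene lists (rows, with the number of genes tested) in the Sohlh1 knockout (red) and Sohlh2 knockout (blue) against wild type. Filled points had camera adjusted p under 0.05 at the preset correlation. With an estimated correlation only the differentiating and oocyte lists passed in both, and the cell cycle list in the Sohlh1 knockout. The differentiating spermatogonia list lay at -0.58 and -0.43 and the germ cell list at -0.20 and -0.04; without the array labelled Sohlh2 knockout 1, which the plot includes, the former lay at -0.73 in the Sohlh2 knockout.

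Between the arrays labelled Sohlh2 knockout and those labelled Sohlh1 knockout, no named gene differed. limma called 0 of 13702 genes, and 390 genes had an unadjusted p under 0.05 where 685 are expected by chance. These counts include the 2 arrays whose targeted genes went against the labels, so they do not show that the knockouts are alike. Sohlh1 had a log2 fold change of 1.46 (SE 0.54) and Sohlh2 of -1.84 (SE 0.86), each with an adjusted p of 1.00. Npy, which rose in the Sohlh1 knockout, had a difference of -1.53 (SE 0.41) between the knockouts and did not pass either. Without the 2 arrays whose targeted genes went against the labels, 4 genes differed: Sohlh2 (-3.82, SE 0.19), Cap1 (-1.15), Zfp386 (1.11) and Sohlh1 (2.65, SE 0.18). The 2 arrays were left out because of their Sohlh1 and Sohlh2 values, so the calls and SEs of Sohlh1 and Sohlh2 there are no test of a difference. Cap1 and Zfp386 fall outside the rule for named genes and were chosen after their values were seen.

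Gene lists gave small shifts between the labelled knockouts. Differentiating spermatogonia (median 0.15, camera adjusted p = 0.000790), cell cycle (0.089) and meiosis genes (0.10) were among 6 germ cell or proliferation lists that were higher in the Sohlh2 knockout. The leukocyte list was higher too (0.10), and the Sertoli (-0.12), Leydig (-0.13) and immediate early (-0.10) lists were lower. None of these 10 lists passed with an estimated correlation, the smallest adjusted p being 0.203, and no member of any of them passed on its own. Leaving out 1 array ended the call for every list but cell cycle, which in turn ended without the 2 arrays whose targeted genes went against the labels (median 0.040, adjusted p = 0.117). Without the array labelled Sohlh2 knockout 1 this held for differentiating spermatogonia (adjusted p = 0.0639), and without the array labelled Sohlh1 knockout 4 or Sohlh2 knockout 1 for Sertoli cells (up to 0.101). Meiosis genes lost it without the array labelled Sohlh1 knockout 4 or Sohlh2 knockout 1 or 4 (up to 0.140), and Leydig genes without the array labelled Sohlh1 knockout 2 or 4 or Sohlh2 knockout 3-1 or 5 (up to 0.0676). Undifferentiated, germ cell, oocyte, leukocyte and immediate early genes lost it in 3, 3, 9, 6 and 4 of 12 such fits. Leaving out 1 array moved the median by over 1.5 times for every one of these lists but Leydig cells, as from 0.15 to 0.084 for differentiating spermatogonia without the array labelled Sohlh2 knockout 1 and from 0.089 to 0.14 for cell cycle without the array labelled Sohlh1 knockout 2.

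The effects of the knockouts ran together across genes. Of the 609 and 514 changed genes 376 changed in both, 142 higher in both and 234 lower in both, with 0 in opposite directions. Independent lists of these sizes would share 3.85 and 7.92 genes, and 100 simulated draws of unchanged groups against the same wild-type arrays shared 0, which is no chance level for this count, since unchanged groups give few calls to share. Across all tested genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.779 (0.502 in the simulated groups) and a covariance of 0.0749 (0.0220 simulated, a difference of 0.0529). With the wild-type arrays split 2 and 2 between the comparisons, in 6 ways, the correlation was 0.385 to 0.486, the covariance 0.0471 to 0.0558 and the number of shared genes 85 to 124. The number of shared genes was 212, 213 or 209 without wild type 4, 5 or 6 and 238 without the array labelled Sohlh2 knockout 4. The array labelled Sohlh1 knockout 5 and that labelled Sohlh2 knockout 1 had targeted genes against their labels, and without both of them the number of genes changed in both knockouts was 344, and 368 without all 3 doubted arrays.

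**Figure D4:**
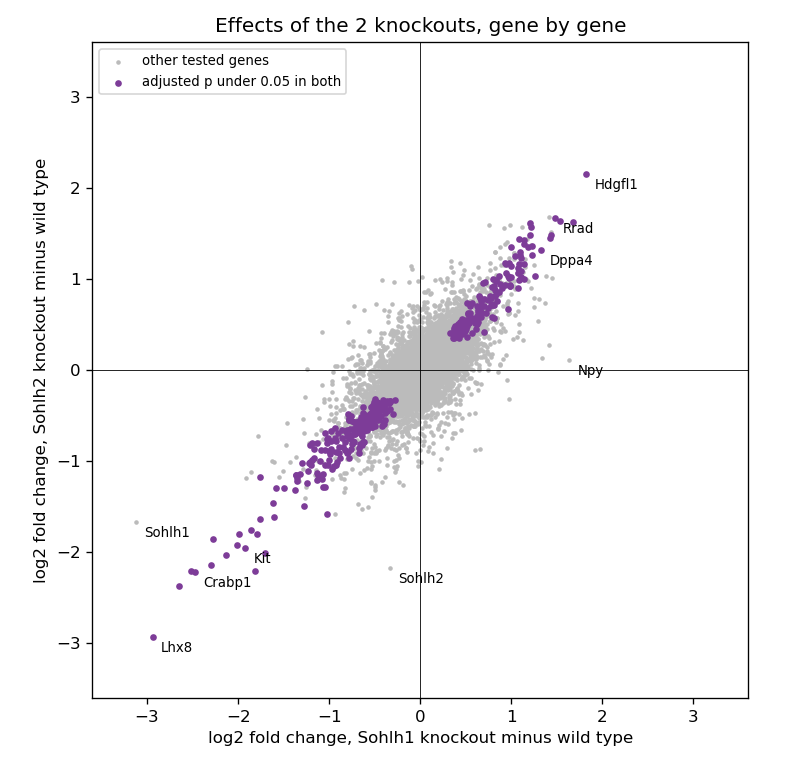
Log2 fold change of each tested gene in the Sohlh1 knockout (horizontal) and the Sohlh2 knockout (vertical) against the same 4 wild-type arrays; purple points are the 376 genes changed in both. All 376 lay in the lower left or upper right, with Lhx8 at -2.94 and -2.93 and Hdgfl1 at 1.82 and 2.16.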

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

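Tests chosen only after the result was seen were those of wild-type RNA mixed into 2 arrays, of germ cells of every stage, whose list had been seen in camera before its median, and of the fits without particular arrays. The fits with the 3' to 5' ratio and with the 18S signal as covariates were added after those values had been seen but before the fits were run, the second in place of a listed test of leaving out 3 arrays, whose value is given with it.

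Sohlh1 and Sohlh2 each had an array far from the others of its group: Sohlh1 lay -1.89 log2 units from the mean of the other 3 arrays on the array labelled Sohlh2 knockout 1, and Sohlh2 lay -3.93 on the array labelled Sohlh1 knockout 5. A mixture with wild-type RNA is argued against, since the gene that each label does not target lay below every wild-type and same-label array, by at least 1.77 log2 units (value -1.77). On these 2 arrays both targeted genes read near the other knockout's arrays. The array labelled Sohlh1 knockout 5 had Sohlh1 at 595 and Sohlh2 at 94.4. The arrays labelled Sohlh2 knockout 3-1, 4 and 5 had 465 to 563 and 73.2 to 157. The array labelled Sohlh2 knockout 1 had 126 and 1847. The arrays labelled Sohlh1 knockout 2, 3 and 4 had 50.2 to 104 and 1556 to 1783. These values raised the question of an exchange of the 2 labels, so they are no separate test of it. An exchange stays open. The 65 tested neighbours of the targeted genes, without those genes, gave a score of -1.21. A score of -1 means that the 2 arrays differed by as much as the other knockout arrays but the other way. Random sets of as many genes had a middle value of -0.449 and a central range of -1.23 to 0.260. An exchange would move those genes too, so they give no reference without one. Cap1 and Zfp386, found without these 2 arrays, went the other way on them (Cap1 -1.15 between the other knockout arrays and 1.28 between these 2, Zfp386 1.11 and -1.49), and of the splits of the 8 knockout arrays the one that an exchange would give called the most genes, 14. An error in single samples was not tested apart from an exchange, and no biological explanation was tested.

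The fall of the differentiating spermatogonia list was weighed against a loss of germ cells of every stage and against RNA quality. The median of the germ cell list was at most 0.343 of that of the differentiating list. Their members differed in both comparisons (permutation p = 0.00183 in the Sohlh1 and 0.00545 in the Sohlh2 knockout, 100000 resamples, two-sided). That permutation takes genes as replicates, so its p does not measure the spread between pools. Both comparisons also share the wild-type arrays, and members of the germ cell list moved both ways. Without the 2 arrays against the labels the medians in the Sohlh1 knockout were -0.28 and -0.66, and the germ cell list passed downward (camera adjusted p = 0.0380). The medians argue against an equal loss of all stages as the whole cause, while a smaller loss of every stage stays open. With the 3' to 5' ratio as a covariate the differentiating list kept 1.25 times its median or more, and with the 18S control signal 0.997, with camera adjusted p of at most 2.05e-12 and 1.27e-08. Without the 3 doubted arrays its medians were -0.57 and -0.73, with adjusted p of 0.0359 and 0.0594 with an estimated correlation, so that the call in the Sohlh2 knockout (0.0210 with all arrays) ended there. A lower number of differentiating spermatogonia and a lower transcript level per cell both remain open, since whole testes cannot separate them. The list's fall may therefore be biological, as a hypothesis found on the same data.

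Chance as the source of the groupings was examined with all 35 splits of the 8 arrays of each comparison. For the Sohlh1 knockout against wild type 1 of 35 splits, the real one, gave as many as 609 genes, and the highest other split gave 0. For the Sohlh2 knockout against wild type it was again 1 of 35, with 514 genes against 0. A share of 1 in 35 is the smallest that these splits can give. Every other split mixed wild-type and knockout arrays, which widens the spread within its groups. The splits thus argue against chance for both comparisons but do not exclude it, and both comparisons use the same wild-type arrays. For the comparison between the knockouts 35 of 35 splits gave at least the real count of 0, which a real count of 0 fixes, so this says nothing about chance. The highest other split gave 14 genes and the next 1. The split with 14 set the arrays labelled Sohlh1 knockout 2, 3 and 4 and Sohlh2 knockout 1 against the other 4, which points to a structure of the samples. This is the grouping that an exchange of the labels of the 2 arrays against them would give, and the targeted genes themselves were among the genes tested. That split also put the 2 arrays of high 3' to 5' ratio (2.71 and 1.26) on one side, and what the structure follows was not tested.

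Single arrays stood apart from the other 3 of their group in 13 of 99 sets examined, where chance gives about 4.95, or about 1 in 20 groups. Besides the targeted genes, in wild type these were Arhgap9 on array 3 (0.86 log2 units from the mean of the others), Lhx8 on array 3 (-0.32), Tbx4 on array 5 (0.96), Hoxb6 on array 4 (1.00) and Runx3 on array 5 (0.36). On the array labelled Sohlh1 knockout 2 these were Dlx1 (1.00), Tbx4 (-1.57) and the 18S control signal (6.42). The array labelled Sohlh2 knockout 3-1 stood apart in Dmrtb1 (-1.14), the array labelled Sohlh2 knockout 5 in Mypn (0.58) and the array labelled Sohlh2 knockout 1 in the mean log2 ratio of 3' to 5' controls (2.26).

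Differences between the effects of the knockouts, tested directly with camera, passed for 10 lists. Medians in the Sohlh2 knockout minus the Sohlh1 knockout were 0.10 for undifferentiated spermatogonia, 0.15 for differentiating spermatogonia, 0.071 for germ cells of any stage, 0.10 for meiosis, 0.14 for oocyte genes, 0.089 for cell cycle and 0.10 for leukocytes. They were -0.12 for Sertoli cells, -0.13 for Leydig cells and -0.10 for immediate early genes. With an estimated correlation none of the 10 passed.

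Probe sets without a single named gene, which the comparisons of genes do not use, also held changes. Of 3788 tested, 46 changed in the Sohlh1 knockout (18 higher, 28 lower) and 39 in the Sohlh2 knockout (18 higher, 21 lower).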

How the results depend on the processing

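Fits without the 2 arrays whose targeted genes went against the labels, without the 2 arrays of high 3' to 5' ratio, without all 3, and with that ratio as a covariate were chosen after seeing the data. Of 98 results for named genes 51 kept their call under every alternative that gave a value, 47 lost it under at least 1, and 2 turned: with probe sets that can match several transcripts left out, Piwil4 in the Sohlh1 knockout had -0.14 and Lss 0.18, since another probe set stood for each. The stricter filter gave no value for 21 of the 98, and leaving out those probe sets none for Aurkb. Sohlh1 and Sohlh2 have 1 probe set each, so averaging probe sets could not change them. Where no reason is given, the cause was not tested. Array signals near background limit what can be seen of dim genes.

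The number of genes changed in the Sohlh1 knockout was 375 with the mean of all probe sets of a gene, 1086 with array weights, 213 at an adjusted p under 0.01 and 299 with at least 1.5-fold change, against 609. It was 322 to 970 when 1 array was left out. In the Sohlh2 knockout it was 1020 with array weights, 184 at an adjusted p under 0.01 and 283 with at least 1.5-fold change, against 514, and 264 to 561 with 1 array left out. The number of genes changed in both knockouts was 693, 142 and 214 under the same 3 alternatives, a mean of 101.2 with the wild-type arrays split, which leaves fewer arrays per comparison, and 209 to 394 with 1 array left out. Between the knockouts 4 genes passed without the 2 arrays against the labels and 4 without all 3, and 0 with any 1 array left out. The first 4 include Sohlh1 and Sohlh2, by whose values the 2 arrays were picked.

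The correlation of the knockout effects was 0.739 without a log offset, 0.827 with an offset at the median, 0.695 without a filter, 0.857 with a stricter filter and 0.447 on average with split wild-type arrays. It was 0.719 to 0.812 with 1 array left out, 0.662 without the 2 arrays against the labels, 0.722 without the 2 of high 3' to 5' ratio and 0.644 without all 3. Gene lists past the threshold fell from 5 to 3 in the Sohlh1 knockout, from 7 to 2 in the Sohlh2 knockout and from 10 to 0 between the knockouts with an estimated correlation, and from 10 to 0 between the knockouts with fry. Between the knockouts there were 4 to 10 lists with 1 array left out, 6 without the 2 arrays against the labels, 2 without the 2 of high ratio and 5 without all 3.

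Sohlh2 in the Sohlh1 knockout went from -0.33 to 0.65 without the 2 arrays against the labels, to 0.69 without all 3 (adjusted p = 0.0854, not passed), and lay between -0.70 and 0.65 with 1 array left out. Sohlh1 in the Sohlh2 knockout was -1.66 and passed in the fit of only the 2 groups compared. It passed at -1.19 without the 2 arrays against the labels and without all 3, and lay between -1.87 and -1.19 with 1 array left out, passing at -1.66 without the array labelled Sohlh1 knockout 5 (adjusted p = 0.0124), which enters that comparison through the spread alone. Sohlh2 in the Sohlh2 knockout passed at -3.01 with array weights, at -2.93 with the ratio as a covariate, and at -3.17 without the 2 arrays against the labels, without the 2 of high ratio or without all 3. It lay between -3.17 and -1.70 with 1 array left out, passing without the array labelled Sohlh2 knockout 1 (adjusted p = 0.0141). The 2 arrays against the labels were picked by their Sohlh1 and Sohlh2 values. Calls of these genes made without either array are therefore no test of them.

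No pairing by replicate number was seen: the deviations of 7 pairs of arrays with the same number correlated at -0.0349 to 0.0793, and those of 41 other pairs at -0.190 to 0.281. A link between arrays of the same number is not excluded, since the pairs are few and some hold an array of doubted label. With the replicate block and 3-1 as its own number, 148 genes changed in the Sohlh2 knockout, 134 in both, the correlation of the effects was 0.691, 6 lists passed between the knockouts and the ribosomal list turned to -0.083 there (adjusted p = 0.0314). With the replicate block and 3-1 read as 3, the correlation was 0.725, 4 lists passed between the knockouts and Sohlh2 in the Sohlh2 knockout passed at -3.11.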

Other observations

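The tests of leukocytes, whose list had been seen in camera before its median, of mast cell genes and of the X chromosome were chosen after the result was seen, and the last was repeated without the genes that had prompted it after its first result was known.

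Magea5 rose from 499 ± 64.0 to 1188 ± 126 in the Sohlh1 knockout and 1241 ± 279 in the Sohlh2 knockout (SD, n = 4 each), and Mageb3 from 178 ± 24.9 to 396 ± 53.0 and 459 ± 62.5. Magea6 and Dppa4 rose in both, while Dppa2 passed in the Sohlh2 knockout (adjusted p = 0.0297) and not in the Sohlh1 knockout (adjusted p = 0.0607), a difference that itself did not pass (log2 0.27, SE 0.41). The Dppa2 call in the Sohlh2 knockout ended without wild type 4 or 6 or the array labelled Sohlh2 knockout 3-1, 4 or 5 (adjusted p up to 0.103). Of 9 tested mast cell genes 3 rose in both knockouts, the proteases Cpa3, Cma1 and Mcpt4: Cpa3 had mean signals of 175 in wild type, 381 in the Sohlh1 and 451 in the Sohlh2 knockout, Cma1 135, 262 and 314, and Mcpt4 109, 236 and 295. The other 6 did not pass. Among these Tpsab1 had mean signals of 201, 391.6 and 526 (adjusted p = 0.182 and 0.0665), Tpsb2 had log2 fold changes of 0.51 and 0.72, Gata2 0.064 and 0.14, and Hpgds -0.51 and -0.35.

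Genes on the X chromosome made up 3.54% of 13679 tested genes with a known chromosome, 8.71% (21 of 241) of those that rose in the Sohlh1 knockout and 6.39% (14 of 219) in the Sohlh2 knockout (Fisher's exact test, two-sided, p = 0.000134 and 0.0388). Those counts hold Magea5 and Magea6, which lie on the X and were among the 6 genes that prompted the test. Without these 6 genes the shares were 3.53% of tested genes, 8.05% (19 of 236) and 5.63% (12 of 213), with p = 0.000902 and 0.0925 in the same exact test. The exact test takes genes as independent replicates, so its p-values do not measure the spread between pools. Whether X-linked genes rise more often than others therefore stays open: it passed in the Sohlh1 knockout and not in the Sohlh2 knockout, a difference that was not itself tested, and the comparisons share their wild-type arrays. Among genes that fell the shares were 2.99% and 4.41% (same exact test, p = 0.668 and 0.423).

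The higher values of Magea5, Magea6, Mageb3, Dppa2, Dppa4 and Hdgfl1, a set put together after their values were seen, with medians of 1.37 and 1.39 and with Dppa2 not past the threshold in the Sohlh1 knockout, were set against a larger share of blood cells. A larger share of the leukocytes marked by the leukocyte list, many of whose 16 genes are macrophage genes, is argued against. That list had a median of at most 0.0576 times that of the 6 genes, and its highest member was at 0.35. Leukocytes that the list does not mark were not tested. For mast cells the 9 tested genes had medians of 0.51 and 0.72, or 0.371 and 0.521 times that of the 6 genes. The first ratio lay below the higher bound set for the test and the second above it. Ratios of this kind cannot name the cells that hold the 6 genes, so no conclusion on mast cells is drawn. Dppa4, among the 6, was on the fixed list of germ cells of any stage. The prediction on mast cells first named them and other leukocytes together with a bound on leukocytes alone, and was divided once the mast cell values were seen. Whether the 6 genes are read in mast cells was not tested.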
